A study of Mus musculus with 4 samples.

How the data were processed

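The samples were regulatory T cells (Tregs) of 2 mice bearing tumors, each surgically joined to a tumor-free partner so that the pair shared blood. Per the labels, the partner's cells were told apart by their lack of the congenic CD45.1 allele. They were sorted as live CD45.2-positive, B220-negative, CD4-positive and CD25-positive cells carrying the green fluorescent reporter of Foxp3. Omental tumors and spleens gave 2 libraries each, from mouse 2 and mouse 3 in both tissues, at day 14 after tumor cell injection. Per the labels' protocols, total RNA was turned into cDNA with the SMART-seq v4 kit, which amplifies full-length transcripts from small inputs, and into libraries by Nextera XT tagmentation. Neither kit marks the strand of the transcript.

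The deposited values are whole-number read counts per gene symbol, in 1 file for each library. Per the submitters' processing notes, Trim Galore, TopHat2, SAMtools and HTSeq were used with the mouse genome build mm10. Their versions, the gene annotation and the strand setting are not given in the sources used here. Each file ends with 5 HTSeq summary entries that name no gene, and these were kept out of library sizes and tests. Entries outside annotated genes made up 48.9% and 27.3% of the omental tumor files of mouse 2 and mouse 3, and 44.2% and 24.8% of the spleen files. Alignments that were not unique made up 33.5% and 49.9% of the omental files and 30.3% and 28.0% of the spleen files. Reads assigned to more than 1 gene made up 0.442% and 0.649% in omental tumor and 0.665% and 1.22% in spleen. Genes received the remaining 17.1% and 22.2% in omental tumor, and 24.9% and 46.0% in spleen. Both omental libraries held fewer counts in genes than either spleen library, so low transcripts are measured with more counting error there.

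The counts of 24421 genes were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at a minimum count of 10, which left 16322. Libraries were scaled by TMM factors of 1.15 and 1.05 for omental tumor and 1.03 and 0.804 for spleen, and levels are given as CPM, counts scaled by these effective library sizes, as mean ± SD with n = 2. Omental tumor was compared with spleen by edgeR's quasi-likelihood test (estimateDisp, glmQLFit and glmQLFTest with default settings) with Benjamini-Hochberg adjustment at 0.05. The model held the tissue alone, leaving 2 residual degrees of freedom, and positive log2 fold changes mean higher in omental tumor. Adjusted p-values without another name come from this test. SE is the absolute log2 fold change divided by the square root of the test's F statistic. The prior degrees of freedom of the dispersion were infinite in this fit. Neither the SE nor the p-value therefore measures a gene's own spread between mice. Fixed gene lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1, two-sided, on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 41 lists. Of these, 25 held biological themes of Tregs, 13 markers of other cell types and 3 genes that follow handling or RNA quality. Camera was repeated with an estimated correlation, and fry tested whether each list moved on balance in one direction.

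The mouse numbers come from the labels and mark the same animal in both tissues, so they were taken to pair the samples. Deviations from the tissue means correlated at 0.234 across genes between libraries of the same mouse. With 2 libraries per tissue the crossed mouse numbers must give the mirror value, -0.234, so this adds little to the labels. A fit with the mouse as a replicate block was the first alternative, calling 261 genes.

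The test design, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined, and the analysis departed from none of them. The genes open to naming were the sort markers Foxp3, Il2ra, Cd4 and Ptprc. To these were added the 10 largest rises and the 10 largest falls among genes past adjusted p 0.05 that moved the same way in both mice, with a mean above 32 CPM in the higher tissue. The rule further took the 4 members with the smallest p-values in each biological list, and the 2 most abundant members of each list of other cells or quality. Genes named outside this rule are said to be so, and 1 gene within it is not reported here. The alternative settings were RLE and upper-quartile factors, library totals alone, no filter on low counts, a minimum count of 50, DESeq2 1.42.0, limma-voom, the legacy and robust forms of glmQLFit, the replicate block, an adjusted p of 0.01, glmTreat against a fold of 1.5, and leaving out each library in turn. In the last, the lone library of a tissue was assumed to vary like the other tissue's pair. DESeq2 gave no adjusted p for 3481 genes, which were left without a call. Removal of the trend with gene length or GC content from each library, and the removal of 3 very abundant features or of the other-cell genes, were added after seeing the data, as was a set of 18 T lineage genes.

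The fit was tested on simulated data, with counts drawn for the 16322 genes from these libraries' means and sizes in 5 sets, each with 200 changed genes. The omental tumor against spleen test called 0% of 2-fold, 4.18% of 4-fold and 53.0% of 16-fold changes, with 10 calls among 75685 unchanged genes. A list shifted 4-fold was called in 5 of the 5 sets, and other lists were called 1 time in all. Each gene was drawn independently at the trended dispersion, without correlation within lists or transcripts particular to a single library. These rates therefore do not describe the errors to be met where the real libraries hold such features. 

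The gene totals lay between 3764508 and 13598631 counts per library. No molecular identifiers were used per the labels, so PCR copies cannot be told from separate molecules. Gene positions are from GENCODE version M21 on GRCm38, the same build as mm10, matched by symbol for 23334 genes and by an older symbol for 667, while 420 had no single match. The files hold symbols and no coordinates. Because strand is not recorded, reads where a gene overlaps another on the opposite strand cannot be assigned with certainty. Such overlaps cover 27.1% of Il5 exons (with Gm12214), 26.8% of Ctsl exons (with Gm47123), 12.9% of Foxp3 exons (with Ccdc22) and 9.5% of Evl exons (with Degs2). Any other opposite-strand overlap with a single gene covers at most 8.1% of the exons of a gene given with a test value. On the same strand, Flicr overlaps 18.6% of Foxp3 exons. Counts of closely related copies, among them Lyz1 and Lyz2, are uncertain to the extent that reads align to both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.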

Results

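Transcriptomes were measured in Tregs that had travelled from a tumor-free partner into a parabiotic mouse carrying EG7.1.15 tumor cells in the peritoneal cavity. The omentum is a fold of visceral fat with lymphoid clusters in the abdomen, where peritoneal tumor cells lodge, and the spleen of the same mouse served as the reference tissue. The question was how Tregs that home to omental tumors differ from those that home to the spleen. There were 2 libraries per tissue, from mouse 2 and mouse 3. Omental tumor libraries held 6660230 and 3764508 counts in genes for mouse 2 and mouse 3, and spleen libraries 9989005 and 13598631. Across genes, which are not independent replicates, Spearman's rho was 0.932 between the spleen libraries and 0.849 between the omental libraries. The mouse 2 omental library correlated with the spleen library of that mouse at 0.915, more closely than with the other omental library.

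**Figure D1:**
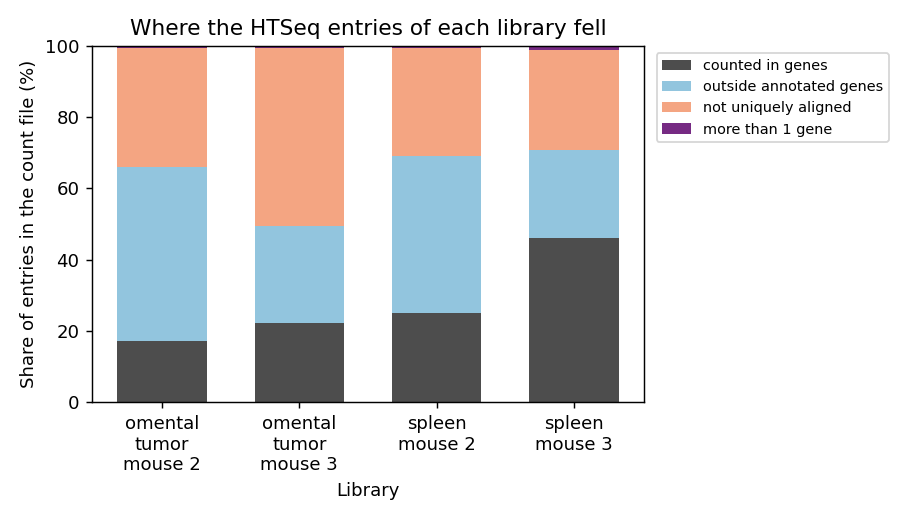
Share of the entries of each count file (percent, stacked bars) that fell in genes, outside annotated genes, on more than 1 alignment site or on more than 1 gene, for the 4 libraries. Genes received 17.1% and 22.2% in omental tumor and 24.9% and 46.0% in spleen, and the share outside genes was higher in both libraries of mouse 2 (48.9% and 44.2%) than of mouse 3 (27.3% and 24.8%).

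The markers used for sorting were present in all 4 libraries. Foxp3, the lineage-defining transcription factor of Tregs (chromosome X, 7573644 to 7595245), stood at 82.8 ± 2.07 CPM in omental tumor and 129 ± 22.3 CPM in spleen (SD, n = 2). Il2ra, which encodes CD25 (chromosome 2, 11642807 to 11693193), stood at 505 ± 262 and 793 ± 132 CPM. Cd4 stood at 245 ± 185 and 788 ± 311 CPM, and Ptprc, which encodes the pan-leukocyte antigen CD45, at 1501 ± 814 and 3315 ± 1017 CPM. None of the 4 differed past the threshold in edgeR's quasi-likelihood test. Their log2 fold changes were -0.64 (adjusted p = 0.772), -0.65 (0.799), -1.68 (0.503) and -1.14 (0.744). All 4 were lower in omental tumor than in spleen in both mice. On simulated data the test called 0% of 2-fold and 4.18% of 4-fold changes, so missing the threshold does not show equal levels.

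Libraries of sorted Tregs from omental tumors differed from those of spleen in 233 of 16322 genes, of which 190 were higher and 43 lower in omental tumor. This fit left out the pairing by mouse, and 152 of the 233 were also called with the replicate block (124 higher, 28 lower). The smallest called change had an absolute log2 fold change of 2.64, and 1673 genes had an unadjusted p under 0.05. Of the higher genes, 176 were higher in both mice, and all 43 lower genes were lower in both. The omental libraries were uneven, since 89 of the 190 higher genes stood over 5 times higher in mouse 3 than in mouse 2, 16 the other way round, and 85 within that ratio. Calls numbered 273 without the omental library of mouse 2 and 77 without that of mouse 3, 60 without the spleen library of mouse 2 and 97 without that of mouse 3. With upper-quartile factors 210 genes were higher and 13 lower, and with library totals alone 26 and 2, against 190 and 43.

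The largest rise was in Irg1, now named Acod1, the macrophage enzyme that makes itaconate (chromosome 14, 103046977 to 103056573). It reached 848 ± 886 CPM in omental tumor against 0.421 ± 0.181 in spleen, a log2 fold change of 10.91 (SE 1.32, adjusted p = 2.57e-12). The neutrophil-attracting chemokine Cxcl2 (chromosome 5, 90903871 to 90905938) rose by 8.45 on the log2 scale, from 1.02 ± 1.02 to 365 ± 446 CPM. The monocyte-attracting chemokine Ccl8 rose by 8.24 and Thbs1, a matrix protein that activates latent TGF-beta, by 8.23. Interleukin-1 beta and its receptor antagonist rose side by side, Il1b by 8.08 (636 ± 825 against 2.34 ± 0.847 CPM) and Il1rn by 7.48 (645 ± 819 against 3.57 ± 2.84 CPM). Areg, the epidermal growth factor family ligand that tissue Tregs use in repair, rose by 7.53 (SE 1.02, 346 ± 382 against 1.86 ± 0.824 CPM). Hcar2, a receptor for niacin and ketone bodies, rose by 7.56, the histamine-making enzyme Hdc by 7.38 and the complement C5a receptor C5ar1 by 7.19. Each of the 10 was higher in the mouse 3 than in the mouse 2 omental library, and the neutrophil marker S100a9 stood in those libraries at 475 and 1.58 CPM. Without the omental library of mouse 3 the adjusted p was 0.198 for Ccl8, 0.810 for Hcar2, 0.227 for Hdc and 0.252 for C5ar1. The other 6 passed the threshold without any single library, the highest adjusted p being 0.0389 for Thbs1. Their log2 fold changes without the omental library of mouse 3 were lower, at 8.89 for Irg1, 5.48 for Cxcl2, 5.27 for Areg, 4.41 for Il1b, 4.28 for Thbs1 and 4.09 for Il1rn, and those of Ccl8, Hcar2, Hdc and C5ar1 were 4.36, 1.07, 3.75 and 4.43.

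**Figure D2:**
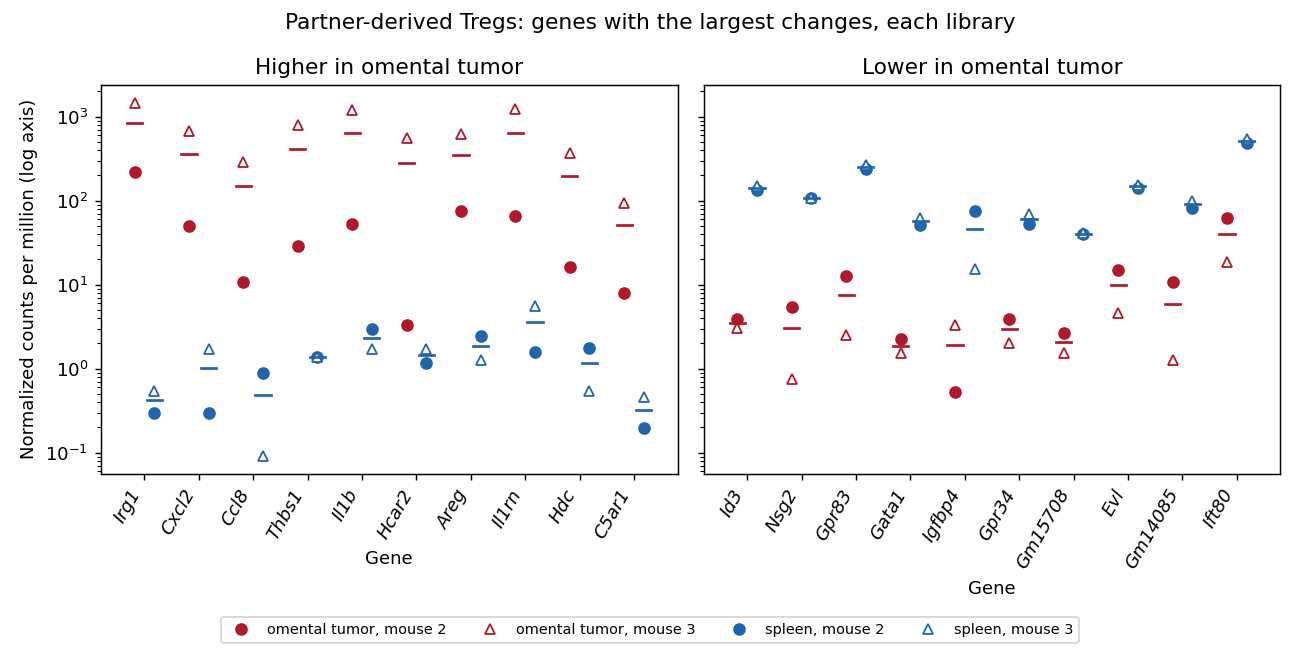
Normalized CPM (log axis) of the 10 genes with the largest rise and the 10 with the largest fall, with a symbol for each library (filled circles mouse 2, open triangles mouse 3; red omental tumor, blue spleen) and bars for the means of 2. Omental values of the higher genes differ widely between mice (Irg1 221 and 1474 CPM), while spleen values of most lower genes lie close together (Id3 134 and 150 CPM).

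The largest fall was in Id3, an inhibitor of E proteins that is high in resting and central Tregs (chromosome 4, 136143497 to 136145755). It stood at 3.49 ± 0.636 CPM in omental tumor and 142 ± 11.4 CPM in spleen, a log2 fold change of -5.32 (SE 0.907, adjusted p = 2.31e-06). Nsg2, a neuronal vesicle protein gene also seen in naive T cells, fell by 5.01, from 107 ± 1.25 to 3.07 ± 3.27 CPM. Gpr83, a receptor typical of resting Tregs, fell to 7.57 ± 7.12 CPM from 251 ± 18.6 CPM (log2 fold change -5.00). Gata1, a transcription factor best known from red cell and mast cell development, fell by 4.87 (56.9 ± 8.67 against 1.88 ± 0.504 CPM). Igfbp4, an insulin-like growth factor binding protein of naive T cells, fell by 4.73 and the lysophospholipid receptor gene Gpr34 by 4.30. Over the libraries left out in turn, log2 fold changes ran from -6.48 to -3.11 for Igfbp4 and from -7.13 to -4.40 for Nsg2. The actin regulator Evl fell by 3.89 and the cilium transport gene Ift80 by 3.67, with Gm15708 (-4.23) and Gm14085 (-3.86) making up the 10. Id3, Nsg2, Gpr83 and Gata1 passed the threshold without any single library, the highest adjusted p being 0.0425 for Gata1 without the omental library of mouse 3. Igfbp4 lost its call without the omental (adjusted p = 0.119) or spleen library of mouse 2 (0.465), and Gm15708 without the omental library of mouse 2 (0.0803). Without the omental library of mouse 3 the adjusted p was 0.0908 for Gpr34, 0.176 for Gm15708, 0.154 for Evl, 0.227 for Gm14085 and 0.420 for Ift80. Without the spleen library of mouse 2 it was 0.0649 for Gm15708 and for Evl, 0.0624 for Gm14085 and 0.151 for Ift80, which also missed the threshold without the spleen library of mouse 3 (0.166).

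Genes of resting and central Tregs, which recirculate through lymphoid organs, were lower in omental tumor as a group. Of 25 genes tested, 24 had negative log2 fold changes, with a median of -2.36 over both mice, -2.11 in mouse 2 and -2.45 in mouse 3. Over all genes tested 7 fell and 1 rose, and adjusted over the list alone 15 fell and 1 rose. The list passed camera with the preset correlation (adjusted p = 1.12e-15), while adjusted p = 0.536 with an estimated correlation. The median of 18 T lineage genes, such as those of the CD3 complex, was also negative in the same libraries, at -1.13 (log2 ratios of -0.76 in mouse 2 and -1.68 in mouse 3). Neutrophil markers were higher, with a list median of 2.43 (log2 ratios of 0.52 in mouse 2 and 3.01 in mouse 3). Fibroblast markers were higher too, at 2.99 (2.57 and 0.82). Besides Id3, Gpr83 and Igfbp4, the survival factor Bcl2 fell from 267 ± 55.5 to 24.5 ± 8.47 CPM (log2 fold change -3.44, adjusted p = 0.00414). S1pr1, the receptor that lets T cells leave lymphoid tissue, fell from 932 ± 207 to 95.6 ± 80.5 CPM (-3.28, adjusted p = 0.0337). The lymph node homing receptor gene Ccr7 missed the threshold (-1.64, adjusted p = 0.487). The member that rose, Ramp3, is a partner of the calcitonin-family receptors and stood at 91.8 ± 52.1 against 3.49 ± 0.369 CPM (4.71, adjusted p = 2.56e-05). Bcl2 and S1pr1 lost their calls when any 1 of the 4 libraries was left out, with adjusted p from 0.0651 to 0.253 and from 0.0537 to 0.745. Igfbp4 lost its call without the omental (0.119) or spleen library of mouse 2 (0.465), and Ramp3 without the spleen library of mouse 2 (0.202) or mouse 3 (0.0570). The list itself passed without each library in turn, with adjusted p at most 1.14e-10.

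Genes typical of visceral fat and tissue Tregs were higher in omental tumor, with a median log2 fold change of 1.57 over 24 genes, 23 of them positive. Of these, 6 rose over all genes tested and 10 rose adjusted over the list alone. The list passed camera (adjusted p = 2.84e-10), and adjusted p = 0.536 with an estimated correlation. Areg and Cxcl2 led the list, and both enzymes of the last step of triglyceride synthesis rose with them. Dgat2 went from 12.0 ± 13.1 to 221 ± 96.4 CPM (log2 fold change 4.20, adjusted p = 0.000166) and Dgat1 from 25.8 ± 6.78 to 356 ± 234 CPM (3.78, adjusted p = 0.00152). Nfil3, a basic leucine zipper regulator of effector T cells, rose by 4.82 to 62.5 ± 67.4 CPM. By mouse, the median log2 ratio of the visceral fat and tissue list was 1.87 in mouse 2 and 1.13 in mouse 3. Markers of neutrophils and fibroblasts were higher in the same libraries, with list medians of 2.43 and 2.99. The log2 ratios of neutrophil markers were 0.52 in mouse 2 and 3.01 in mouse 3, and those of fibroblast markers 2.57 and 0.82. Without the spleen library of mouse 3 the adjusted p was 0.441 for Dgat2 and 0.495 for Dgat1, and 0.349 for Dgat1 without that of mouse 2. Nfil3 lost its call without the omental library of mouse 3 (0.645) or the spleen library of mouse 2 (0.287), and the list passed without each library, with adjusted p at most 0.000311.

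Lists of effector, tumor and suppressive Tregs shifted upward, and few of their members passed singly. Effector Treg genes had a median of 0.67 over 30 genes, with 2 called over all genes tested, Nfil3 and Bhlhe40, and 3 adjusted over the list alone (camera adjusted p = 0.0310, adjusted p = 0.937 with an estimated correlation). Bhlhe40, a basic helix-loop-helix regulator of cytokine production, rose from 95.4 ± 64.2 to 795 ± 308 CPM, and its log2 fold change of 3.06 (adjusted p = 0.0494) became 3.19 (adjusted p = 0.0628) with the replicate block. It also lost its call when any 1 library was left out, with adjusted p from 0.0740 to 0.524. The cytolytic enzyme Gzmb stood at 619 ± 121 against 137 ± 79.3 CPM (2.17, adjusted p = 0.275) and Id2 at 1238 ± 892 against 187 ± 114 CPM (2.73, adjusted p = 0.169). Tumor Treg genes had a median of 1.13 over 23 genes, with 20 positive and 0 called in edgeR, both over all genes tested and adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.898 with an estimated correlation). Among them, the chemokine receptor gene Ccr8 stood at 492 ± 161 against 126 ± 96.8 CPM (1.97, adjusted p = 0.337) and the decoy receptor gene Il1r2 at 354 ± 191 against 84.5 ± 82.3 CPM (2.07, adjusted p = 0.260). Suppressive mediators had a median of 0.77 over 20 genes, with Areg called and 5 rising adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.644 with an estimated correlation). Il12a, which encodes a subunit of interleukin-35, stood at 4.43 ± 1.25 against 0.0947 ± 0.00449 CPM (5.31, adjusted p = 0.0627) and was called with the replicate block (adjusted p = 0.00177). Type 2 genes had a median of 0.96 over 13 genes, with 2 called, Areg and Il5, and 5 adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.536 with an estimated correlation). Il5, which encodes interleukin-5, stood at 6.33 ± 3.57 against 0.147 ± 0.208 CPM (5.29, adjusted p = 0.0306), and lost its call without any 1 library (0.0630 to 0.409). The neutrophil list stood higher in the same libraries, with a median of 2.43 (log2 ratios of 0.52 in mouse 2 and 3.01 in mouse 3). Camera no longer passed for effector genes without the omental library of mouse 3 (adjusted p = 0.788) or the spleen library of mouse 2, where the direction turned (0.513). The same libraries ended the calls of tumor Treg genes (0.463, and 0.943 with the direction turned) and of suppressive mediators (0.141 and 0.286), while type 2 genes missed without the spleen library of mouse 2 (0.0802).

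**Figure D3:**
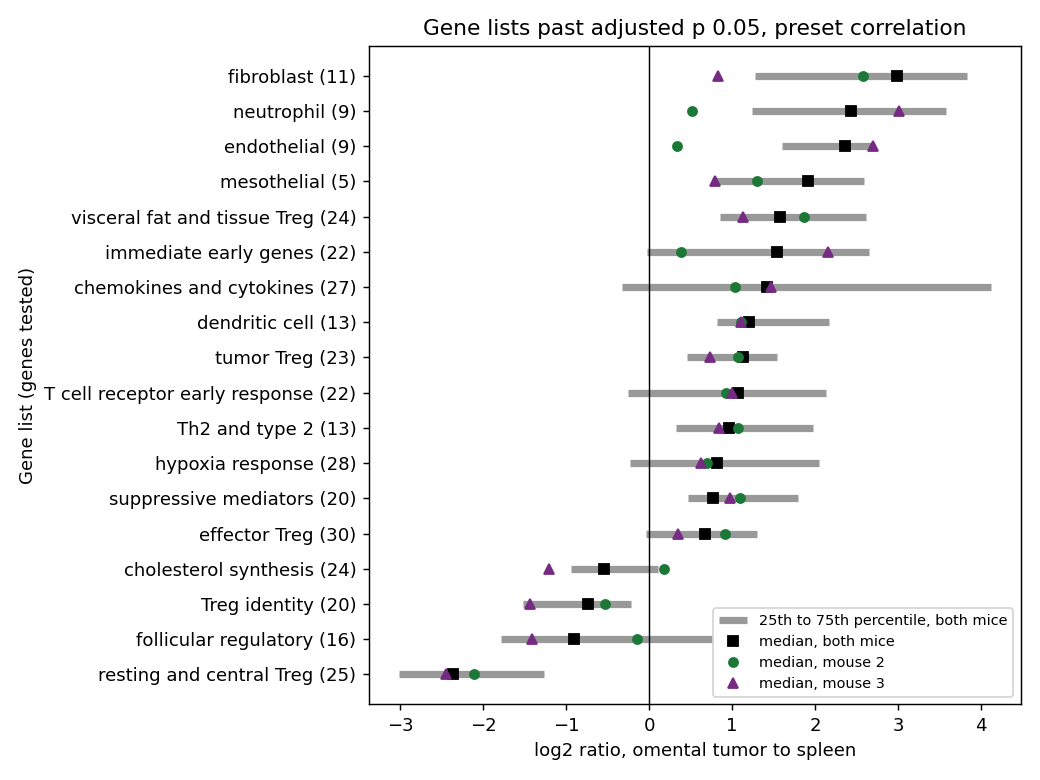
Log2 ratio of omental tumor to spleen for the 18 gene lists past adjusted p 0.05 in camera with the preset correlation, with genes tested in parentheses. Squares and gray bars are the median and the 25th to 75th percentile of fitted log2 fold changes, and circles and triangles the medians of log2 ratios of CPM plus 1 within mouse 2 and mouse 3. The resting and central list lies near -2 in both mice (-2.11 and -2.45), the neutrophil list is higher in mouse 3 (3.01) than in mouse 2 (0.52), and none of the lists passed with an estimated correlation (smallest adjusted p 0.536).

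Chemokine and cytokine genes were higher in omental tumor, as were several markers of myeloid cells. Of 27 chemokines and cytokines tested, 7 rose and Lta, a lymphotoxin chosen after its values were seen as the single member that fell, was lower (-3.03, adjusted p = 0.0180). Adjusted over the list alone 10 rose and 3 fell, with a median of 1.42 (camera adjusted p = 3.71e-05, adjusted p = 0.644 with an estimated correlation). The macrophage inflammatory proteins Ccl3 and Ccl4 rose by 5.36 (191 ± 242 against 4.62 ± 2.66 CPM) and 5.73 (541 ± 725 against 10.2 ± 3.86 CPM). Their log2 fold changes were only 1.98 and 1.40 without the omental library of mouse 3. Ccr1, the receptor of Ccl3 and Ccl4, rose by 4.47 (212 ± 218 against 9.52 ± 1.42 CPM) and the chemerin-binding receptor Ccrl2 by 3.88. S1pr4, a receptor for sphingosine 1-phosphate, fell by 2.72 (adjusted p = 0.0404). With S1pr1, 2 chemokine receptor genes rose and 2 fell of 24, and 6 rose and 5 fell adjusted over the list alone (median 0.71, camera adjusted p = 0.535). Without the omental library of mouse 3 the adjusted p was 0.802 for Ccl3 and Ccl4, 0.349 for Ccr1 and 0.227 for Ccrl2. Without the spleen library of mouse 2 it was 0.169, 0.165, 0.263 and 0.471 in that order, and without that of mouse 3 it was 0.0643 for Ccl4, 0.105 for Ccr1 and 0.265 for Ccrl2. S1pr4, S1pr1 and Lta missed without any 1 library, with adjusted p from 0.0978 to 0.619, from 0.0537 to 0.745 and from 0.0760 to 0.371. The replicate block gave S1pr4 a log2 fold change of -2.83 (adjusted p = 0.0795).

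Neutrophil markers had a median log2 fold change of 2.43 over 9 genes, with 0.52 in mouse 2 and 3.01 in mouse 3. Over all genes tested 4 rose and adjusted over the list alone 6 rose (camera adjusted p = 0.00227, adjusted p = 0.644 with an estimated correlation). The calgranulin genes S100a8 and S100a9 stood at 0.131 and 1.58 CPM in the omental library of mouse 2 and at 412 and 475 CPM in that of mouse 3, against 7.89 ± 2.30 and 8.30 ± 1.13 CPM in spleen. Csf3r (152 ± 176 against 13.3 ± 12.0 CPM) and Retnlg (21.1 ± 24.9 against 1.74 ± 1.69 CPM), both chosen after their values were seen as the remaining called members, were also highest in the omental library of mouse 3. With the replicate block none of the 4 was called: the log2 fold change was 1.07 for S100a8 (adjusted p = 0.846), 1.92 for S100a9 (0.637), 3.07 for Csf3r (0.204) and 3.04 for Retnlg (0.140). Without the omental library of mouse 3 the adjusted p of these 4 lay between 0.645 and 0.817, with log2 fold changes of -5.86 for S100a8 and -2.47 for S100a9. Without the spleen library of mouse 2 their adjusted p lay between 0.155 and 0.242, and without that of mouse 3 between 0.0655 and 0.522. The neutrophil list missed without the omental library of mouse 3, with the direction turned (adjusted p = 0.788), or without the spleen library of mouse 2 (0.0607). Macrophage and monocyte markers did not shift as a group, with a median of -0.19, a mean of 0.71 and camera pointing upward (adjusted p = 0.173). In that list Lyz2, Cd14 and Lyz1 were called of 16, and 5 rose adjusted over the list alone, while Ctss, its most abundant member, stood at 304 ± 94.3 against 415 ± 131 CPM. Cd14 (5.30) and Lyz1 (3.27) were chosen after their values were seen, and Lyz2 stood at 274 ± 33.3 against 34.3 ± 38.8 CPM (2.99, adjusted p = 0.0194). Lyz2 lost its call without the omental library of mouse 3 (0.0945) or either spleen library (0.534 and 0.0700), and Cd14 and Lyz1 without the omental library of mouse 3 (0.586 and 0.647) or the spleen library of mouse 2 (0.160 and 0.505). The macrophage list passed without the omental library of mouse 2 (0.0134) and without the spleen library of mouse 3 (2.81e-05).

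Genes induced early after T cell receptor engagement were higher in omental tumor, with a median of 1.07 over 22 genes. Of these 4 rose over all genes tested, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0142, adjusted p = 0.536 with an estimated correlation). The orphan nuclear receptors Nr4a2 (61.7 ± 15.6 against 3.74 ± 4.12 CPM, log2 fold change 4.05, adjusted p = 0.000737) and Nr4a3 (111 ± 50.4 against 8.16 ± 3.13 CPM, 3.77, adjusted p = 0.000991) rose with Bhlhe40 and the phosphatase gene Dusp4 (3.02, adjusted p = 0.0180). Immediate early genes, which also answer to tissue dissociation, had a median of 1.54 over 22 genes, with 0.38 in mouse 2 and 2.15 in mouse 3. Among them 4 rose over all genes tested and 8 adjusted over the list alone (camera adjusted p = 3.57e-05, adjusted p = 0.536 with an estimated correlation). The called members, chosen after their values were seen, were Atf3 (6.36), Fosl2 (5.62), Ier3 (5.13) and Dusp1 (3.90). Their log2 fold changes without the omental library of mouse 3 were 5.76, 5.80, 1.27 and 0.88 in that order. Junb and Rgs1, the most abundant members, had log2 fold changes of 1.62 and 0.17 and were not called. Blocking by mouse (replicate block), the log2 fold change of Dusp4 was 3.20 (adjusted p = 0.0570), and adjusted p was 0.0628 for Bhlhe40 and 0.206 for Dusp1. Leaving out the omental library of mouse 3, the adjusted p was 0.0517 for Nr4a3, 0.494 for Dusp4, 0.802 for Ier3 and 0.804 for Dusp1, and Bhlhe40 missed without any 1 library (0.0740 to 0.524). Without the spleen library of mouse 2 it was 0.264 for Nr4a3, 0.263 for Dusp4, 0.102 for Fosl2 and 0.198 for Ier3 and Dusp1, and without that of mouse 3 it was 0.335 for Nr4a2, 0.291 for Nr4a3, 0.646 for Dusp4 and 0.390 for Dusp1. The receptor response list missed without the omental library of mouse 3 (0.194) or the spleen library of mouse 2 (0.280), and the immediate early list without the omental library of mouse 3 (0.138).

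Hypoxia response genes had a median log2 fold change of 0.82 over 28 genes, with 2 called and 4 rising adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.536 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose from 9.04 ± 0.228 to 89.4 ± 18.9 CPM (3.30, adjusted p = 0.00611). Hilpda, a lipid droplet protein induced by low oxygen, rose from 28.5 ± 4.0 to 246 ± 160 CPM (3.11, adjusted p = 0.0122). Immediate early genes were higher in the same libraries, with a median of 1.54. In the lipid uptake and storage list 3 of 32 genes rose, Dgat1, Dgat2 and the fatty acid carrier Fabp4 (3.86, adjusted p = 0.0118), and 5 adjusted over the list alone. That list had a median of -0.35, a mean of 0.33 and camera pointing upward (adjusted p = 0.676). Asparagine synthetase, Asns, rose by 2.81 (329 ± 97.2 against 46.9 ± 0.116 CPM, adjusted p = 0.0405), as the single call among 23 genes of the unfolded protein response, also adjusted over the list alone (median 0.17, camera adjusted p = 0.384). The log2 fold changes with the replicate block were 2.94 for Hilpda (adjusted p = 0.0747), 2.78 for Asns (0.0917) and 2.78 for Fabp4 (0.145). Egln3, Hilpda, Asns and Fabp4 missed without the omental library of mouse 3 (adjusted p = 0.0823, 0.476, 0.296 and 0.889), the spleen library of mouse 2 (0.454, 0.477, 0.490 and 0.354) or that of mouse 3 (0.324, 0.451, 0.686 and 0.115). Dgat1 missed without either spleen library (0.349 and 0.495) and Dgat2 without that of mouse 3 (0.441). The hypoxia list missed without the omental library of mouse 3 (0.367) or the spleen library of mouse 2 (0.513).

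Genes of Treg identity were somewhat lower in omental tumor, with a median of -0.74 over 20 genes and 16 negative. Only Gpr83 was called among them, both over all genes tested and adjusted over the list alone (camera adjusted p = 0.00147, adjusted p = 0.656 with an estimated correlation). The list's median log2 ratio was -0.53 in mouse 2 and -1.44 in mouse 3. The 18 T lineage genes had medians of -0.76 and -1.68, so the identity list fell no further than T lineage genes. Of these 18, 4 are also in the fixed lists, so the sets compared may share members. The surface receptor Nrp1 stood at 130 ± 95.7 against 503 ± 139 CPM (-1.94, adjusted p = 0.349), the folate receptor family member Izumo1r at 143 ± 56.2 against 553 ± 99.7 CPM (-1.96, adjusted p = 0.353) and the transcription factor gene Ikzf4 at 78.4 ± 79.4 against 276 ± 71.1 CPM (-1.81, adjusted p = 0.355). Follicular regulatory genes had a median of -0.91 over 16 genes, with 2 falling, and 4 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0333, adjusted p = 0.845 with an estimated correlation). These were Id3 and the ATP-gated channel gene P2rx7, which fell from 238 ± 43.2 to 30.6 ± 17.8 CPM (-2.95, adjusted p = 0.0213), while Cxcr5 stood at 10.2 ± 9.10 against 66.5 ± 21.4 CPM (-2.66, adjusted p = 0.0611). Cholesterol synthesis genes had a median of -0.54 over 24 genes, with 0 called in edgeR over all genes tested or adjusted over the list alone (camera adjusted p = 0.0416, adjusted p = 0.905 with an estimated correlation). By mouse, the median log2 ratio of cholesterol synthesis genes was 0.18 in mouse 2 and -1.21 in mouse 3, opposite in direction. That of follicular regulatory genes was -0.14 in mouse 2 and -1.42 in mouse 3. Fibroblast and neutrophil markers were higher in the same libraries, with medians of 2.99 and 2.43. Log2 ratios in mouse 2 and mouse 3 were 2.57 and 0.82 for fibroblast markers and 0.52 and 3.01 for neutrophil markers. P2rx7 fell by 3.07 with the replicate block (adjusted p = 0.0664), and it missed without any 1 library (0.0726 to 0.547). The follicular list missed without the omental library of mouse 2 (0.0732) or the spleen library of mouse 3 (0.451), and the cholesterol list without the omental (0.0776) or spleen library of mouse 3 (0.547).

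Interferon response genes did not shift as a group, with a median of -0.27 over 46 genes, a mean of 0.22 and camera pointing downward (adjusted p = 0.249). Of these 4 rose over all genes tested and 6 adjusted over the list alone. The antiviral genes Rsad2, Oasl1 and Ifit3 stood at 20.5, 3.81 and 10.2 CPM in the omental library of mouse 2 and at 2176, 263 and 511 CPM in that of mouse 3, against 19.4 ± 4.83, 15.2 ± 2.62 and 34.2 ± 5.33 CPM in spleen. The chemokine Cxcl10 was higher in both, at 128 and 971 against 19.0 ± 14.5 CPM (4.85, adjusted p = 5.46e-05). S100a9 was likewise higher in the omental library of mouse 3 (475 CPM) than in that of mouse 2 (1.58 CPM). With the replicate block the log2 fold changes were 3.49 for Rsad2 (adjusted p = 0.187), 1.15 for Oasl1 (0.680) and 1.12 for Ifit3 (0.678). They were -0.011, -2.08 and -1.83 without the omental library of mouse 3, where Cxcl10 had adjusted p = 0.145. The 4 genes also missed without the spleen library of mouse 2 (adjusted p from 0.201 to 0.489) or mouse 3 (0.0766 to 0.497). The list passed upward without the omental library of mouse 2 (0.0134), and downward without that of mouse 3 (2.86e-08) or without the spleen library of mouse 2 (0.01), and downward without a filter on low counts (0.0153).

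Markers of stromal and antigen-presenting cells were higher in the omental libraries although the gate was for CD4-positive Foxp3-reporter cells. Fibroblast genes had a median of 2.99 over 11 genes, with 3 called and 7 adjusted over the list alone (camera adjusted p = 4.43e-05, adjusted p = 0.644 with an estimated correlation). Fn1 stood at 103 and 8.86 CPM in the omental libraries of mouse 2 and mouse 3 against 3.69 ± 4.19 CPM in spleen. Col3a1 (46.6 ± 63.1 against 2.24 ± 0.574 CPM) and Sparc (39.4 ± 35.5 against 0.734 ± 1.04 CPM) were chosen after their values were seen as the remaining called members. The most abundant member, Thy1, which T cells also express, had a log2 fold change of -0.41 (adjusted p = 0.851), which turned to 0.18 with upper-quartile factors. Mesothelial genes had a median of 1.91 over 5 genes with Upk1b called, also adjusted over the list alone (40.0 ± 29.0 against 3.62 ± 3.05 CPM, camera adjusted p = 0.0105, adjusted p = 0.644 with an estimated correlation). Endothelial genes had a median of 2.36 over 9 genes with 0 called in edgeR, and 4 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.000603, adjusted p = 0.536 with an estimated correlation). The endothelial list had a median log2 ratio of 0.33 in mouse 2 and 2.7 in mouse 3. Its most abundant member Pecam1 stood lower, at 55.6 ± 34.6 against 231 ± 33.2 CPM (-2.05, adjusted p = 0.241). Vwf stood at 18.1 ± 1.19 against 3.09 ± 2.55 CPM, a log2 fold change of 2.55 (adjusted p = 0.224) that was called with the replicate block (adjusted p = 0.0403). Dendritic cell genes had a median of 1.21 over 13 genes, with 3 called and 4 adjusted over the list alone (camera adjusted p = 0.00269, adjusted p = 0.644 with an estimated correlation). The 3 were the class II genes H2-Aa (2.64), H2-Ab1 (2.84) and H2-Eb1 (2.71), chosen after their values were seen. The most abundant members of the list were not called. Ccr7 was lower (-1.64, adjusted p = 0.487). Cd74 stood at 599 and 232 CPM in the omental libraries of mouse 2 and mouse 3 against 167 and 306 CPM in their spleen libraries.

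Several of the stromal and class II calls were lost when 1 library was left out. Leaving out the omental library of mouse 2, the adjusted p was 0.769 for Fn1, 0.994 for Col3a1 (log2 fold change -0.15), 0.213 for Upk1b, 0.322 for H2-Aa, 0.365 for H2-Ab1 and 0.203 for H2-Eb1, and without that of mouse 3 it was 0.161 for Sparc. Without the spleen library of mouse 2 it lay between 0.202 and 0.484 for Upk1b, Col3a1 and the 3 class II genes, and without that of mouse 3 between 0.128 and 0.741 for these and Fn1. With the replicate block the log2 fold change of Fn1 was 3.78 (adjusted p = 0.00806), while Col3a1 (adjusted p = 0.177), H2-Aa (0.132), H2-Ab1 (0.135) and H2-Eb1 (0.0907) were not called. The dendritic and mesothelial lists missed without the omental library of mouse 2 (0.141 and 0.220), while fibroblast and endothelial genes passed without each library (at most 0.00452 and 0.00397).

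The remaining lists did not pass camera. Oxidative phosphorylation genes had a median of 0.62 with 0 of 67 called in edgeR (adjusted p = 0.0811), proliferation genes 0.07 with 0 of 49 (adjusted p = 0.535) and glycolysis genes -0.06 with 0 of 23 (mean 0.11, camera upward, adjusted p = 0.939). Adhesion genes (-0.68, adjusted p = 0.102), Th1 genes (0.27, adjusted p = 0.809) and Th17 genes (0.23, adjusted p = 0.676) gave 0 calls over all genes tested, and 1 Th17 gene fell adjusted over the list alone. The interleukin-6 receptor gene Il6ra, of the Th17 list, stood at 3.85 ± 0.995 against 30.8 ± 19.5 CPM (-3.02, adjusted p = 0.0633) and was called with the replicate block (adjusted p = 0.0486). Apoptosis and survival genes had a median of -0.30 (adjusted p = 0.173) with Bcl2 as the single call, also adjusted over the list alone. The list of TNF receptor family members and other costimulatory receptors such as Icos had a median of -0.21 and a mean of 0.03 (camera downward, adjusted p = 0.939). In it, Tnfrsf9 stood at 1605 ± 385 against 519 ± 184 CPM and Icos at 1103 ± 181 against 395 ± 205 CPM. Neither was called (adjusted p = 0.585 and 0.598). Inhibitory receptors had a median of 0.49 and a mean of -0.34 (camera downward, adjusted p = 0.384). Among other cells, B cell (0.79, adjusted p = 0.540), plasma cell (0.71, adjusted p = 0.802), CD8 T and NK cell (0.79, adjusted p = 0.350) and mast cell and basophil genes (0.20, adjusted p = 0.676) gave 0 calls over all genes tested, and B and plasma cell lists 1 rise each adjusted over the list alone. Erythroid genes had a median of -0.01 and a mean of 0.28 (camera upward, adjusted p = 0.996). Adipocyte genes (0.61, adjusted p = 0.939) had Fabp4 as their call, and immature T cell genes (0.79, adjusted p = 0.711) the protease gene Ctsl (105 ± 93.0 against 14.3 ± 1.20 CPM). Adjusted over the list alone Fabp4 and Ctsl passed as well, and 1 immature T cell gene fell. Ctsl and Fabp4 were not called with the replicate block (log2 fold change 2.52, adjusted p = 0.137, and 2.78, adjusted p = 0.145), nor without the omental library of mouse 3 (0.802 and 0.889) or either spleen library (0.115 to 0.486). Bcl2 missed without any 1 library (0.0651 to 0.253). Heat shock (0.55, adjusted p = 0.176) and cytosolic ribosomal protein genes (0.24, adjusted p = 0.996) gave 0 calls. With upper-quartile factors, library totals alone or a minimum count of 50 the oxidative phosphorylation list passed upward (0.0252, 0.0131 and 5.22e-05). The ribosomal list passed downward without the omental library of mouse 3 (1.92e-07) and the oxidative phosphorylation list likewise (0.00464), and both passed upward without that of mouse 2 (0.000205 and 1.26e-06) or the spleen library of mouse 3 (0.0123 and 1.10e-06). The proliferation list passed downward without the spleen library of mouse 2 (0.0366) and upward without that of mouse 3 (5.23e-06). Upward without the spleen library of mouse 3 were also chemokine receptor (0.00399) and heat shock genes (0.0257), and without the omental library of mouse 3 B cell (0.00877), mast cell and basophil (0.0165) and plasma cell genes (0.0251). Apoptosis and survival genes passed downward without the omental library of mouse 3 (0.0165) or the spleen library of mouse 2 (0.0164), and adhesion genes without the latter (0.0315).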

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

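The read shares below lie outside the gene comparison, were compared only after they were seen, and were not put to a test. The share of entries outside annotated genes was 48.9% in the omental tumor library of mouse 2, above both spleen libraries (44.2% and 24.8%), while that of mouse 3 stood at 27.3%. The share of alignments that were not unique was 33.5% in the omental tumor library of mouse 2 and 49.9% in that of mouse 3, both above the spleen libraries at 30.3% and 28.0%. The ribosomal precursor feature Rn45s took 4.86% of the gene counts in the omental library of mouse 3, and 1.14%, 1.23% and 0.798% in the omental library of mouse 2 and the spleen libraries of mouse 2 and mouse 3.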

How the results depend on the processing

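The removal of length or GC trends, of 3 abundant features and of other-cell genes was chosen only after the results were seen. The count of 233 genes stayed within 1.5 times under RLE factors (261), upper-quartile factors (223), limma-voom (163), the legacy (215) and robust (244) fits, glmTreat (185) and the replicate block (261, of which 152 shared). It also did so without Rn45s and 2 other abundant features (234) and without other-cell genes (217). DESeq2 called 370 genes, 124 of them lower, and limma-voom 107 higher. Lower genes numbered 13 with upper-quartile factors, 26 under glmTreat and 26 with the GC trend removed. At adjusted p 0.01 there were 146 calls, 17 lower. Library totals alone gave 28 (26 higher, 2 lower). A minimum count of 50 gave 4 (4 higher, 0 lower), Irg1 among them. There Areg, Cxcl2, Il1b, Thbs1, Il1rn, Id3, Nsg2, Gpr83 and Gata1 missed, with edgeR adjusted p from 0.0503 to 0.0770. Without a filter edgeR called 0 genes (0 higher, 0 lower), with 1903 at an unadjusted p under 0.05, against 370 by DESeq2 and 163 by limma-voom on filtered genes. The replicate block gave 2 (2 higher, 0 lower) with the length trend removed and 1 (1 higher, 0 lower) with the GC trend removed. In these settings with under 30 calls the prior degrees of freedom of the dispersion were between 8.54 and 11.3, where they were infinite in the unblocked TMM fit and 25.7 with upper-quartile factors, but the cause of the lower counts was not tested. The median log2 fold change of all genes was 0.13 with TMM, 0.25 with RLE, 0.62 with upper-quartile factors and 0.40 with library totals.

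With a library left out the calls lay between 60 and 273 (53 to 248 higher, 6 to 25 lower), from fewer samples. The count of 18 lists was 11 at adjusted p 0.01, and lay between 15 and 22 in the other settings in which lists were tested except the estimated correlation (0) and fry (0), which allow for correlation within a list; 2 lists had an unadjusted p under 0.05 with the estimated correlation, and fry's smallest adjusted p was 0.0542. Cholesterol synthesis missed with upper-quartile factors (adjusted p = 0.0548) and with the length trend removed (0.0820). Effector Treg genes missed with the length trend removed (0.115) and without a filter (0.112), and the T cell receptor early response list missed without a filter (0.0568). With a minimum count of 50 the endothelial (0.386), follicular regulatory (0.205) and cholesterol synthesis (0.361) lists missed. With the replicate block and the length trend removed the effector Treg (0.122), follicular (0.0727) and cholesterol (0.0722) lists missed. Lists that gained the threshold were oxidative phosphorylation (0.0252 with upper-quartile factors, 0.0131 with library totals alone, 5.22e-05 with a minimum count of 50 and 0.0422 with the replicate block and the GC trend removed), and, without a filter, adhesion (0.0202), apoptosis (0.0249) and interferon response (0.0153), all downward. A minimum count of 50 also brought heat shock (0.0255), unfolded protein response (0.0435), proliferation (0.00963) and ribosomal protein genes (0.0409) past it upward. Direction turned for several results, and the cause was not tested beyond the library left out. The log2 fold change of S100a8 was -0.67 by limma-voom. Upper-quartile factors turned uncalled Thy1 to 0.18 and Ctss to 0.11. Over the libraries left out in turn, log2 fold changes ran from -0.011 to 6.79 for Rsad2, -2.08 to 4.10 for Oasl1, -1.83 to 3.89 for Ifit3, -5.86 to 5.68 for S100a8, -2.47 to 5.83 for S100a9, -0.15 to 5.26 for Col3a1, -1.40 to 0.44 for Thy1, -0.90 to 0.24 for Ctss and -0.087 to 0.70 for Rgs1. Camera's adjusted p ran from 2.86e-08 to 0.221 for interferon response, 5.32e-11 to 0.788 for neutrophil, 1.10e-06 to 0.513 for oxidative phosphorylation, 1.92e-07 to 0.0521 for ribosomal protein, 1.59e-08 to 0.943 for tumor Treg, 9.69e-10 to 0.788 for effector Treg and 5.23e-06 to 0.658 for proliferation genes. Among the values of 90 genes given with a test value in the text, 1363 kept direction and side of the threshold, 561 lost the threshold, 14 gained it and 14 turned. The replicate block (261 calls) changed no call of a named gene or list beyond those given in the report. With 2 libraries per tissue and omental totals of 6660230 and 3764508 counts, most changes of 4-fold or less are below what the test finds. On simulated data it called 0% of 2-fold, 4.18% of 4-fold and 53.0% of 16-fold changes, so many larger changes are missed as well.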

Other observations

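The macrophage test was chosen only after the results were seen. Calls without either omental library in turn numbered 34, 30 higher and 4 lower, and the lower ones were Id3, Gpr83, Nsg2 and Gata1. Among the higher were Irg1, Cxcl2, Thbs1, Il1b, Il1rn, Areg, Atf3, Fosl2, Dgat1, Dgat2, Nr4a2 and Ramp3, together with Rhox5, chosen after its values were seen. Rhox5, a homeobox gene of reproductive tissue on the X chromosome, stood at 153 and 301 CPM in the omental libraries and at 8.91 and 8.42 CPM in spleen (log2 fold change 4.71, adjusted p = 1.97e-05). Trap1a, also X-linked, known as a mouse tumor rejection antigen and also chosen after its values were seen, stood at 50.1 and 81.8 CPM against 10.1 and 1.56 CPM (3.50, adjusted p = 0.00414). Rhox5 lost its call without the spleen library of mouse 2 (0.198) or mouse 3 (0.113), and Trap1a without the omental library of mouse 3 (0.144) or either spleen library (0.0903 and 0.497). Where these transcripts came from was not tested.

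The fall of resting Treg genes was weighed against technical explanations. A trend with transcript length is argued against, since the list median stayed at -2.37 with that trend removed (-2.43 with the replicate block). A smaller T cell share cannot be told apart from a change within Tregs, as the difference of the list median from that of 18 T lineage genes was -1.23 overall but -1.36 in mouse 2 and -0.77 in mouse 3 (permutation test over genes, two-sided p = 0.00181), and the tissue itself stays open as an untested biological cause.

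Pancreatic enzyme transcripts appeared in the omental library of mouse 2, where Pnlip stood at 177 CPM and Prss2 at 164 CPM against at most 1.96 CPM in the other 3 libraries, both genes chosen after their values were seen. Background common to both mouse 2 libraries is argued against by these low spleen levels of Pnlip and Prss2 themselves. Also higher in the omental than in the spleen library of that mouse were 18 of 18 further acinar genes, Try10 only by 5 against 4 counts. Being genes of the same cells, these 18 extend the pattern and are no independent test of it. Their median log2 ratio of 4.20 is consistent with pancreatic RNA or cells carried into that sort, and the most abundant were Cela2a at 173 CPM and Cel at 141 CPM. None of the 18 is in the other lists, 5 were above 1 CPM in a spleen library, and a gate on CD45.2, CD4 and the Foxp3 reporter would remove intact acinar cells. No biological explanation was tested.

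Inflammatory myeloid genes stood highest in the omental library of mouse 3. Tissue macrophages in that sort cannot be told apart from other sources, since members of the macrophage and monocyte list went both ways against the spleen library of that mouse, with 9 of 16 lower and a median log2 ratio of -0.32. Neutrophils in that sort stay open as well, and a comparison of their markers between libraries decides nothing, since these, with S100a9 at 475 CPM, S100a8 at 412 CPM and Csf3r at 276 CPM, are part of what raised the question. The gate on CD4, CD25 and the Foxp3 reporter was set against intact cells of both kinds, as it was against acinar cells. Whether the Tregs of that mouse themselves made these transcripts stays open and was not tested.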
